A study of Rattus norvegicus with 18 samples.

How the data were processed

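Total RNA from primary cultured rat inner medullary collecting duct cells was extracted with a Qiagen RNeasy kit and labelled with biotin after whole-transcript cDNA synthesis with Affymetrix reagents, per the labels' protocols. The array is a rat gene array by the platform's probe gene table. The 18 arrays fall into 6 groups of 3, per the labels: culture at 300 or 600 mosmol/kg, the 300 culture moved to 600 mosmol/kg for 24 h without or with 5 µM cyclosporin A, and the 600 culture moved to 900 mosmol/kg for 24 h without or with 5 µM cyclosporin A. The series text names 4 pairwise comparisons of challenged against unchallenged cultures in BRB ArrayTools and does not name a test.

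The deposited values are log-scale expression values per feature, and neither the labels nor the series text give the base of the logarithm or how the authors summarised and normalized the arrays. They run from 0 to 9.504. The highest value would be an intensity of 726.1 if the log were log2 and 13413.3 if it were a natural log. Array medians between 3.564 and 3.649 show that the arrays had been brought to a common scale, and the distributions are not identical. The test had been planned on log2 values. It was run on the values as deposited, since a change of base scales all differences alike and leaves every p-value as it is. A difference of 1 log unit stands for a 2-fold change with base 2 and a 2.72-fold change with a natural log, so the count given at 1 unit is of changes of at least 2-fold under either base. Of all values, 27 in 16 features are 0, and no filter, background correction or pseudocount was applied. The arrays' signal over background is not given in the sources used here.

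Gene symbols came from the platform's probe gene table: 15295 features have 1 symbol, 322 have several and were not named, and 12711 are not named in the table. Of the features with 1 symbol, 15264 matched a gene of the reference gene table (assembly GRCr8) by Entrez identifier, which was used for names only and changed 0 symbols. The 14499 distinct symbols were each represented in list tests by the feature with the highest mean over all 18 arrays. Genome positions were not used here.

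Differences between groups were tested with limma 3.58.1 in R 4.3.3: a linear model with 6 group means on all 18 arrays, contrasts between groups, moderated variances (residual 12, prior 2.03 and total 14 degrees of freedom) and Benjamini-Hochberg adjustment over all features, with a threshold of 0.05 on the adjusted p. The 8 contrasts were those of the series text, each cyclosporin A group against its challenge without the drug, the 600 culture against the 300 culture, and the 600 challenge against the 600 culture. A pair of further contrasts tested whether the cyclosporin A effect and the osmotic step differed between the 300 and 600 cultures. The genes named for their size of change were the 10 with the largest rise and the 10 with the largest fall among features past the threshold whose 3 values in the groups do not overlap, in each of the first 6 contrasts, and 5 and 5 in the others (without the overlap rule for the differences of effects). Genes with several symbols or with placeholder, olfactory, vomeronasal or small RNA symbols were passed over, and any member of a gene list could be named with its representative feature. This rule, the contrasts, the gene lists and the alternatives were fixed before the data were examined.

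The 24 gene lists held 455 members, of which 414 were measured: osmolyte accumulation, heat shock and chaperones, ion pumps and volume regulation, prostaglandin, principal cell and urine concentration, intercalated cell, loop of Henle, proximal tubule, epithelial junction and keratin, fibroblast and interstitium, endothelium, leukocyte, extracellular matrix and fibrosis, cell cycle, p53 and DNA damage, ER stress and ATF4, sterol synthesis, calcineurin and NFAT, oxidative stress (NRF2), inflammation (NF-kB), interferon response, hypoxia and glycolysis, mitochondrial respiration and reference genes. Lists were tested against all other genes with camera at a preset correlation of 0.01, and again with a correlation estimated per list. List calls given without an estimated-correlation p held with it. The rotation test fry, which asks whether a list's genes move on balance to 1 side, was run as an alternative. Members that rose or fell were counted at the threshold over all features and again adjusted over the list alone.

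Similarity of responses was measured across features as a Pearson correlation and covariance, beside 100 simulations of unchanged groups with the same shared arrays. Independent overlap was the product of the call counts over the number of features. Counts were also taken over other splits of the same arrays. For the differences of effects, the residuals of a fit without the difference were moved between arrays and added back to that fit, so that the main effects stayed in place.

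The limma script was tested on simulated data with 28328 features, of which 67, 67 and 66 differed by 0.25, 0.5 and 1 log unit. For the 600 challenge against the 300 culture it called 16.4%, 37.3% and 80.3% of them with 7.29% false calls, and for the 900 challenge against the 600 culture 10.4%, 37.3% and 83.3% with 4.4% false calls. For cyclosporin A at the 600 challenge it called 19.4%, 52.2% and 77.3% with 5.71% false calls, and at the 900 challenge 11.9%, 43.3% and 80.3% with 10.9% false calls. In 20 draws for cyclosporin A at the 600 challenge, a sterol list shifted by 0.2 was called in 20, and 0 other lists were. The noise was drawn independently for each gene, while the estimated correlation of the cell cycle list, for example, was 0.244. These draws therefore do not show how often lists of correlated genes are called falsely.

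Alternatives were fits of only the groups compared, a replicate block, renewed quantile normalization, centring of arrays on their medians, a filter to features above the median level of 3.607, trended and robust variance moderation, array weights, a plain 2-sample test per feature, 1 feature per gene, and leaving out each array in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were handled with pandas 2.3.3 and numpy 2.4.6.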

Results

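Gene expression was measured in primary cultures of rat inner medullary collecting duct (IMCD) cells, the epithelium at the end of the kidney tubule where urine is concentrated. RNA was read on 18 whole-transcript arrays with 28328 features each. The 6 groups held 3 arrays each. Cells were cultured at 300 mosmol/kg or at 600 mosmol/kg, cells of the 300 culture were moved to 600 mosmol/kg for 24 h (the 600 challenge), and cells of the 600 culture were moved to 900 mosmol/kg for 24 h (the 900 challenge). Each challenge was also run with 5 µM cyclosporin A, an inhibitor of the phosphatase calcineurin. The deposited values are logarithms whose base the sources used here do not give, so differences are in log units, where 1 unit is a 2-fold change if the base is 2 and a 2.72-fold change if the logarithm is natural. Levels ran from 0 to 9.504, and array medians lay between 3.564 and 3.649. The lower quartiles of the arrays lay between 2.476 and 2.696, and levels under them are not shown to stand above background, so differences that start or end there are less sure in size. The median SD between the 3 arrays of a group was 0.108 to 0.123 log units. The first principal component held 44.9% of the variance and ordered the groups from the 300 culture (mean score 41.4) through the 600 challenge (23.2) and the 600 culture (-10.1) to the 900 challenge (-40.9). With cyclosporin A the 600 challenge scored 25.7 and the 900 challenge -39.4. No label says whether the 3 arrays of a group came from separate animals or cultures, so the p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

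The step from 300 to 600 mosmol/kg asked which genes differ in IMCD cells after 24 h of acute hypertonicity. By the labels, no group was given a mock step at unchanged osmolality. For both challenges, hypertonicity thus cannot be told apart from the move itself or from further time in culture. Genes that build up organic osmolytes and move ions were higher after the step, and genes of cell division were lower together with markers of fibroblasts and leukocytes. Among features with a gene symbol the collagenase gene Mmp13 rose most, by 2.80 ± 0.10 log units (SE), from 4.13 ± 0.07 to 6.93 ± 0.25 (SD, n = 3), which is 6.99-fold if the base is 2 and 16.5-fold if it is natural. Akr1b1, the aldose reductase that makes sorbitol, rose by 2.35 ± 0.23 on its more responsive feature and by 1.70 ± 0.06 on its brighter feature. Ptgs2, the inducible cyclooxygenase, rose by 2.00 ± 0.11. The largest falls of such features were in Cnn1, which encodes the smooth muscle protein calponin 1 and went from 5.73 ± 0.03 to 3.02 ± 0.23 (a difference of -2.71 ± 0.15), and in C3ar1, the receptor for the complement fragment C3a (-2.61 ± 0.14).

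Of the 7 measured members of the osmolyte accumulation list, 5 rose and 1 fell after the 600 challenge, also when adjusted over the list alone (median 0.35, camera adjusted p = 0.00124). Besides Akr1b1 the risers were the myo-inositol transporter gene Slc5a3 (0.98), Nfat5, the transcription factor that answers to hypertonicity (0.48), the taurine transporter gene Slc6a6 (0.35) and the amino acid transporter gene Slc38a2 (0.33). Sord, whose enzyme breaks sorbitol down, fell by 0.53. The betaine transporter gene Slc6a12 was among the list members not measured here. In the list of ion pumps and volume regulation, 8 of 16 members rose and the other 8 did not pass the test, with 10 rising when adjusted over the list alone (median 0.17, camera adjusted p = 4.47e-05). They included the Na,K-ATPase subunit genes Fxyd2 (1.54) and Atp1b1 (0.36), the kinase gene Stk39 (0.51) and Slc12a2, the Na-K-2Cl cotransporter that brings ions into shrunken cells (0.49). The heat shock list as a whole did not pass (median 0.04, camera adjusted p = 0.118), although 4 of its 19 members rose and 1 fell. Its risers included Hspa4l (1.37 ± 0.05) and Hsph1 (0.74), both chaperones of the Hsp110 family. The Hsp70 gene Hspa1a of this list was not measured here, so the list result does not cover it. Loop of Henle markers shifted up, with 5 of 10 rising, or 6 when adjusted over the list alone (median 0.33, camera adjusted p = 0.00124, but adjusted p = 0.0775 with an estimated correlation). Among them was the water channel gene Aqp1 (1.18).

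Cell cycle genes fell nearly throughout: 26 of 29 measured members fell after the 600 challenge and the other 3 did not pass, with 27 falling when adjusted over the list alone (median -0.80, camera adjusted p = 2.9e-19). Cdc20, which activates the anaphase-promoting complex, had a difference of -1.50, the ribonucleotide reductase gene Rrm2 -1.47, the cyclin gene Ccnb1 -1.42 and the topoisomerase gene Top2a -1.33. Fibroblast and interstitial markers fell in 11 of 16 cases, also when adjusted over the list alone (median -0.85, camera adjusted p = 1.06e-10), including Postn (-1.45) and the collagen genes Col1a1 (-1.01) and Col3a1 (-1.0). Leukocyte markers fell in 10 of 13 cases, or 11 when adjusted over the list alone (median -1.19, camera adjusted p = 4.16e-12). Examples were the immune adaptor gene Tyrobp (-2.07), the actin regulator gene Coro1a (-1.70) and the macrophage marker Cd68 (-1.61). The 10 largest falls of features with a symbol also held the complement gene C1qa (-2.47), the chemokine gene Ccl6 (-2.43) and Arg1 (-2.18), beside Krt17 (-2.20) and Pi15 (-2.16). Endothelial markers fell in 7 of 13 cases and rose in 1, or 8 and 1 adjusted over the list alone (median -0.28, camera adjusted p = 6.43e-05, but adjusted p = 0.0665 with an estimated correlation). Smaller shifts were seen in the lists of ER stress and ATF4 (1 of 25 rose and 7 fell, median -0.12, camera adjusted p = 0.00955) and extracellular matrix (3 of 19 rose and 9 fell, median -0.19, camera adjusted p = 0.0193, but adjusted p = 0.41 with an estimated correlation). Interferon response genes fell in 7 of 19 (median -0.24, camera adjusted p = 0.0075, but adjusted p = 0.331 with an estimated correlation). Adjusted over the list alone, those counts were 2 and 10, 4 and 10, and 1 and 8.

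Across all features, limma with Benjamini-Hochberg adjustment called 4087 after the 600 challenge, 1801 higher and 2286 lower, of which 87 and 323 differed by at least 1 log unit. Each gene named here for the size of its change had all 3 values of 1 group above all 3 of the other, an order that chance gives in 10% of comparisons of 3 against 3. A plain 2-sample test per feature on the 6 arrays called 2588 features.

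**Figure D1:**
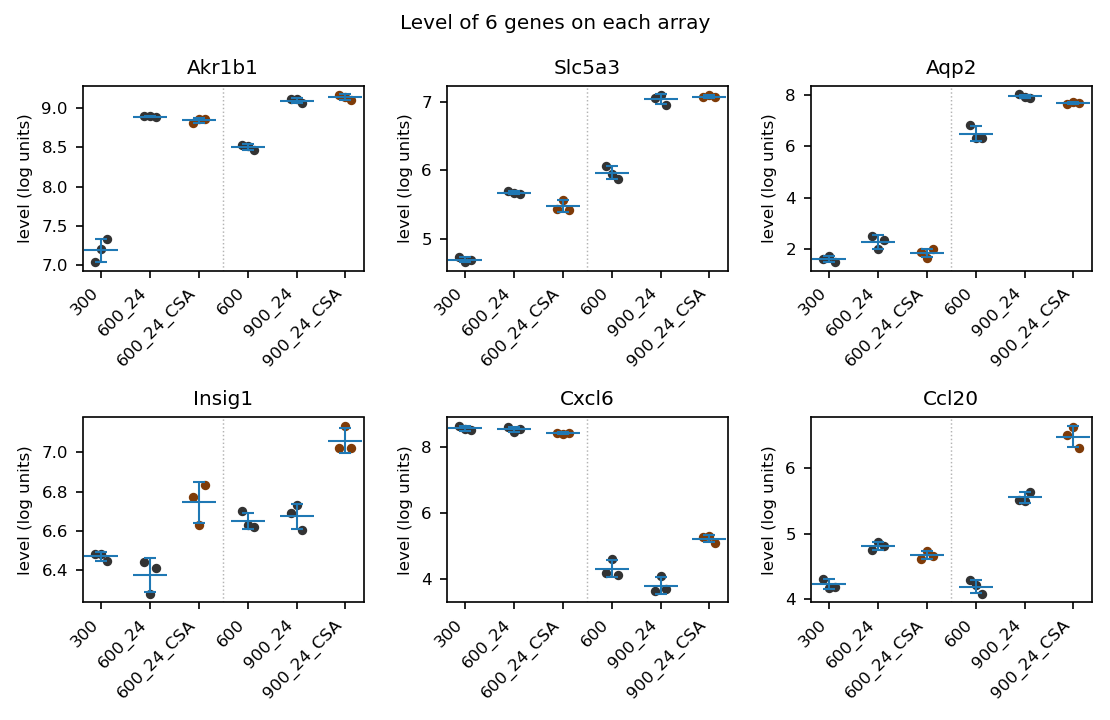
Level in log units of 6 genes on each of the 3 arrays per group, with the group mean as a bar and the SD as whiskers; brown points are arrays with cyclosporin A, and a dotted line parts the groups from the 300 culture (left) from those of the 600 culture (right). Aqp2 had a mean of 1.61 in the 300 culture and 6.50 in the 600 culture, and Cxcl6 had 8.58 and 4.30.

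With cyclosporin A present during the 600 challenge, the response against the 300 culture kept its leading genes. Akr1b1 rose by 2.30 ± 0.23, Mmp13 by 2.29 ± 0.10 (from 4.13 ± 0.07 to 6.42 ± 0.06, SD, n = 3) and Ptgs2 by 2.14 ± 0.11, and Serpinb2, an inhibitor of plasminogen activators, had the largest rise among features with a symbol (2.43 ± 0.27). Among such features Cnn1 showed the largest fall (-2.92 ± 0.15), followed by the antigen presentation gene RT1-DMb (-2.64 ± 0.17) and C3ar1 (-2.63 ± 0.14). Aqp2, the vasopressin-regulated water channel, rose in the challenge without the drug (0.67), and with the drug its difference of 0.24 did not pass the test, nor did the direct difference of -0.43 between these challenges. Its levels there (1.61, 2.28 and 1.86 in the 300 culture and in the challenge without and with the drug) all lay under the lower quartile.

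Osmolyte genes rose in 5 of 7 cases with cyclosporin A (median 0.36, camera adjusted p = 0.00153), with 5 rising and 1 falling when adjusted over the list alone, and Slc5a3 rose by 0.78. Ion pump genes rose in 8 of 16 cases by either adjustment, the second adjusted over the list alone (median 0.13, camera adjusted p = 0.000615). Cell cycle genes fell in 26 of 29 (median -0.67, camera adjusted p = 2.98e-17) and fibroblast genes in 10 of 16 (median -0.70, camera adjusted p = 6.43e-09), both also when adjusted over the list alone. Leukocyte genes fell in 11 of 13, or 12 adjusted over the list alone (median -1.30, camera adjusted p = 4.21e-14). Endothelial genes fell in 9 and rose in 1, or 10 and 1 adjusted over the list alone (median -0.47, camera adjusted p = 1.96e-06). Sterol synthesis genes rose in 8 of 18 cases, also when adjusted over the list alone (median 0.14, camera adjusted p = 0.000615), and without the drug that list had a median of -0.11 (camera adjusted p = 0.167). The sterol genes Cyp51 (0.33) and Sc5d (0.35) and the sterol feedback gene Insig1 (0.28) were among them. Shifts that rested on the preset correlation were those of the loop of Henle (median 0.28, camera adjusted p = 0.0106, but adjusted p = 0.15 with an estimated correlation) and the NRF2 list (median 0.10, camera adjusted p = 0.0188, but adjusted p = 0.221 with an estimated correlation). The interferon list fell with the preset correlation too (median -0.29, camera adjusted p = 0.000282, but adjusted p = 0.16 with an estimated correlation). The same held for the extracellular matrix list (median -0.11, camera adjusted p = 0.0366, but adjusted p = 0.397 with an estimated correlation) and the reference genes (median -0.10, camera adjusted p = 0.0466, but adjusted p = 0.124 with an estimated correlation).

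In this comparison limma called 3982 features, 1759 higher and 2223 lower, with 70 and 302 of them at 1 log unit or more. Of the 4087 features called without the drug, 2933 were also called with it and 2932 of these moved in the same direction, where independent calls would share 112 rises and 179 falls. Of the 87 features that rose by at least 1 log unit without the drug, 79 also rose with it, and their median rise was 1.26 without and 1.19 with it. Of the 323 that fell as far, 310 also fell with the drug (medians -1.24 and -1.21). Both responses use the same 3 arrays of the 300 culture: the correlation of differences across features was 0.841 against 0.499 in simulations of unchanged groups, and the covariance was 0.0755 against 0.0128. The 3 control arrays cannot be split into sets of at least 2 arrays each, so part of the excess in shared calls and in the correlation may come from the shared controls, which the covariance difference of 0.0628 allows for. Fitting only these groups called 2479 features and a plain 2-sample test per feature 2313.

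The step from 600 to 900 mosmol/kg asked the same of cells already grown at the higher osmolality. After it, principal cell, ER stress and prostaglandin genes were higher and fibroblast, leukocyte, matrix and cell cycle genes were lower, again without a mock step beside it. Among features with a symbol Bsnd, the barttin subunit of chloride channels, rose most, by 2.45 ± 0.19 log units from 3.33 ± 0.11 to 5.78 ± 0.19 (SD, n = 3), and S100a5, which encodes a calcium-binding protein, rose by 2.25 ± 0.08. Mmp13 rose by 2.02 ± 0.10 and the solute carrier gene Slc45a3 by 1.88 ± 0.13, as both had in the step from 300 to 600. The metalloproteinase gene Mmp7 (-2.26 ± 0.11), the antimicrobial peptide gene Defb1 (-2.06 ± 0.13) and Cnn1 (-1.98 ± 0.15) had the largest falls among features with a symbol.

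Principal cell and urine concentration genes rose in 11 of 22 cases and fell in 1, also when adjusted over the list alone (median 0.26, camera adjusted p = 1.73e-05). Aqp2 rose by 1.44 to a level of 7.94 ± 0.07, the urea transporter gene Slc14a2 by 1.25, the vasopressin receptor gene Avpr2 by 1.05 and the basolateral water channel gene Aqp3 by 0.78. ER stress and ATF4 genes rose in 15 of 25 cases, or 17 when adjusted over the list alone (median 0.24, camera adjusted p = 1.84e-07), led by the stress kinase-like gene Trib3 (1.13), the glutathione-degrading Chac1 (1.12), Sdf2l1 (0.68) and the transcription factor gene Ddit3 (0.62). Prostaglandin genes rose in 6 of 13, or 7 adjusted over the list alone (median 0.24, camera adjusted p = 5.44e-05): Ptgs2 by 1.77, the prostaglandin E synthase genes Ptges by 1.51 and Ptges2 by 1.04, and Ptgs1 by 0.63. Loop of Henle markers rose in 5 of 10, also when adjusted over the list alone (median 0.29, camera adjusted p = 8.9e-05), with Bsnd and Aqp1 (0.80) among them.

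Osmolyte genes rose in 2 of 7 cases and fell in 1, also when adjusted over the list alone (median 0.09, camera adjusted p = 0.0487, but adjusted p = 0.156 with an estimated correlation). The test of the difference from the step from 300 did not pass for this list (median -0.24, camera adjusted p = 0.0646). Slc5a3 rose by 1.07 and Akr1b1 by 0.59 to 9.10 ± 0.03, and Gdpd5, whose enzyme degrades the osmolyte glycerophosphocholine, fell by 0.40. Interferon response genes rose in 9 of 19 and fell in 2, or 10 and 3 adjusted over the list alone (median 0.28, camera adjusted p = 0.000678, but adjusted p = 0.183 with an estimated correlation). The chaperone list, again without Hspa1a, did not pass as a whole (median 0.02, camera adjusted p = 0.0632), while Hspa4l rose by 1.40 and Hsph1 by 1.05. Leukocyte markers fell in 11 of 13, or 12 adjusted over the list alone (median -1.12, camera adjusted p = 8.1e-11), for example the Fc receptor chain gene Fcer1g (-1.88), the integrin gene Itgam (-1.76) and the macrophage receptor gene Csf1r (-1.53). Fibroblast markers fell in 12 of 16, also when adjusted over the list alone (median -0.66, camera adjusted p = 5.6e-09), with Tagln at -1.19 and Col1a1 at -0.87. Alongside them extracellular matrix genes fell in 14 of 19 and rose in 2, or 15 and 2 adjusted over the list alone (median -0.52, camera adjusted p = 6.33e-08, and adjusted p = 0.0497 with an estimated correlation). Among them were the matricellular genes Ccn1 (-1.35) and Ccn2 (-1.07), the growth factor gene Tgfb2 (-1.15) and the fibronectin gene Fn1 (-1.02). Cell cycle genes fell in 22 of 29, or 28 adjusted over the list alone (median -0.43, camera adjusted p = 6.4e-11, and adjusted p = 0.0497 with an estimated correlation) with Top2a at -1.16.

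The 900 challenge changed 4934 features in the limma test, 1822 up and 3112 down, with 143 and 177 at 1 log unit or more. The share higher of 36.9% became 44.7% of 4541 with the arrays centred on their medians and 44.5% of 4920 after quantile normalization. A fit of only these groups called 2860 and a plain 2-sample test per feature 2593.

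Cyclosporin A during the 900 challenge left the response to the step in place and raised some of its inflammatory genes further. S100a5 rose by 2.56 ± 0.08 (4.13 ± 0.15 to 6.70 ± 0.02, SD, n = 3), Ptgs2 by 2.40 ± 0.11 and Bsnd by 2.38 ± 0.19. The chemokine genes Ccl20 (2.27 ± 0.08) and Cxcl2 (1.95 ± 0.19) and the TNF family gene Tnfsf15 (1.95 ± 0.11) were among the 10 largest rises of features with a symbol. Falls of features with a symbol were led by Cnn1 (-2.74 ± 0.15), Mmp7 (-2.48 ± 0.11), the carbonic anhydrase gene Car3 (-2.37 ± 0.08) and the smooth muscle gene Lmod1 (-2.10 ± 0.22).

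ER stress genes rose in 23 of 25 cases, also when adjusted over the list alone (median 0.44, camera adjusted p = 4.68e-16), with Trib3 at 1.68, Sdf2l1 at 0.92 and the chaperone gene Hspa5 at 0.46. Inflammation genes rose in 10 of 17 and fell in 3 by either adjustment, the second adjusted over the list alone (median 0.45, camera adjusted p = 5.79e-06), with Cxcl1 at 1.47 and Il1b at 1.07. Without the drug 9 had risen and 4 fallen, or 10 and 6 adjusted over the list alone (median 0.19, camera adjusted p = 0.0632), with Ccl20 at 1.35 and Cxcl2 at 0.97. Sterol synthesis genes rose in 10 of 18, or 11 adjusted over the list alone (median 0.27, camera adjusted p = 8.78e-07). NRF2 genes rose in 9 of 19, also when adjusted over the list alone (median 0.18, camera adjusted p = 2.53e-06), led by the cystine transporter gene Slc7a11 (1.21), Me1 (0.87) and the quinone reductase gene Nqo1 (0.86). Heat shock genes rose in 7 of 19 and fell in 1, or 8 and 2 adjusted over the list alone (median 0.08, camera adjusted p = 0.0021), and principal cell genes rose in 9 of 22 and fell in 1, or 9 and 3 adjusted over the list alone (median 0.09, camera adjusted p = 0.0034). Prostaglandin genes rose in 6 of 13, or 7 rose and 1 fell adjusted over the list alone (median 0.20, camera adjusted p = 0.000354), and loop of Henle genes rose in 5 of 10, or 6 adjusted over the list alone (median 0.36, camera adjusted p = 7.38e-05). Leukocyte markers fell in 11 of 13 (median -1.0, camera adjusted p = 7.45e-11) and fibroblast markers in 12 of 16 (median -0.60, camera adjusted p = 5.66e-09), both also when adjusted over the list alone. Calls that were lost with the other correlation were the osmolyte list (median 0.07, camera adjusted p = 0.0355, but adjusted p = 0.104 with an estimated correlation) and the matrix list (median -0.49, camera adjusted p = 8.78e-07, but adjusted p = 0.053 with an estimated correlation). So was that of the cell cycle list, of which 24 of 29 fell (median -0.44, camera adjusted p = 9.68e-10, but adjusted p = 0.0501 with an estimated correlation). The interferon list (median 0.39, camera adjusted p = 3.79e-06, but adjusted p = 0.0657 with an estimated correlation) and the hypoxia and glycolysis list (median 0.09, camera adjusted p = 0.0468, but adjusted p = 0.104 with an estimated correlation) behaved alike in this respect. For the matrix and cell cycle lists the lost call does not show a weaker fall with the drug. Without the drug their medians were -0.52 and -0.43, each with a camera adjusted p = 0.0497 at an estimated correlation.

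In all, limma called 5040 features, 2060 higher and 2980 lower, and 149 and 209 reached 1 log unit. Centring each array on its median moved the split to 53.5% higher among 4710 features. Of the features called without the drug, 3668 were also called with it, 3663 in the same direction, where independent calls would share 132 rises and 327 falls. Of the 143 features up by at least 1 log unit without the drug, 137 also rose with it (medians 1.23 and 1.22), and of 177 down, 174 also fell (medians -1.20 and -1.28). The correlation across features was 0.819 against 0.499 in simulated unchanged groups and the covariance 0.0721 against 0.0128, and part of the excess in calls and correlation may again come from the shared arrays of the 600 culture. A fit of only these groups called 3059 features and a plain 2-sample test per feature 2782.

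The osmotic steps, which share no array, moved many of the same genes. Both raised Mmp13, Ptgs2, Slc5a3 and Hspa4l and lowered Cnn1, Col1a1 and Cd68. Of the features called in each, 2044 were called in both, 639 up and 1204 down in both, against 116 and 251 for independent calls, and 201 moved in opposite directions. Differences across features correlated at r = 0.433 (simulated range for unchanged groups -0.024 to 0.024), features not being independent replicates.

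Where the steps differed, the test of the difference itself called 2148 features, 997 with the higher value in the step from 600 (46.4%), and centring each array on its median turned that share to 54.1% of 1784. Rnf186, a ubiquitin ligase gene, differed by 2.55 ± 0.23 and Ptges by 2.5 ± 0.19, with Ptges at -0.99 in the step from 300 and 1.51 in the step from 600. C3ar1 differed by 2.29 ± 0.20 and Ccl6 by 2.25 ± 0.22, both having fallen in the first step. In the 600 culture they started the second step at 2.67 and 2.48, near the lower quartile of the arrays, against 4.79 and 6.18 in the 300 culture. In the other direction stood Havcr1, the kidney injury molecule gene (-2.03 ± 0.21), the metalloproteinase gene Mmp3 (-1.92 ± 0.21), the cytokine gene Il24 (-1.89 ± 0.26) and Defb1 (-1.83 ± 0.18). ER stress genes were higher in the step from 600 in 14 of 25 cases, or 15 adjusted over the list alone (median 0.29, camera adjusted p = 2.33e-11), Trib3 by 1.58 and the serine synthesis genes Phgdh by 0.96 and Psat1 by 0.93. The lists of inflammation (median 0.36, camera adjusted p = 0.000309), principal cell genes (median 0.22, camera adjusted p = 0.00111) and prostaglandin genes (median 0.18, camera adjusted p = 0.00198) also differed upward. Akr1b1 rose less in the step from 600 (-1.11), where its starting level was already 8.51 ± 0.04 against 7.19 ± 0.15 in the 300 culture. The starting cultures differ as well as the osmolalities, so the steps do not isolate either.

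**Figure D2:**
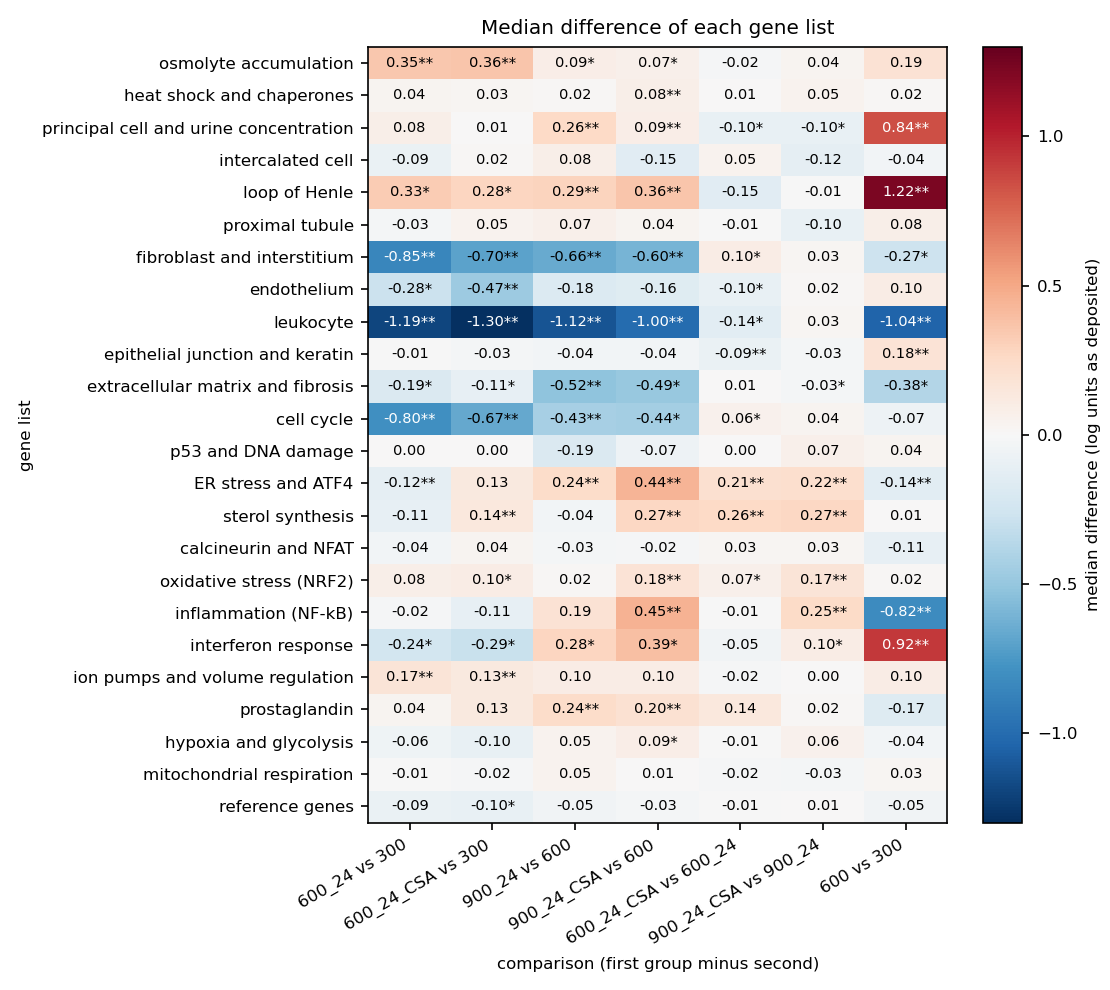
Median difference in log units of 24 gene lists (vertical axis) in 7 comparisons (horizontal axis), first group minus second, with red for higher and blue for lower; 1 star marks a list past camera at adjusted p under 0.05 and a pair of stars a call that also held with an estimated correlation. The leukocyte list had medians of -1.19 and -1.12 after the steps from 300 and from 600, and the sterol synthesis list had 0.26 and 0.27 with cyclosporin A against none.

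Cyclosporin A given with the 600 challenge was compared directly with the challenge alone. No unchallenged culture was given the drug, and no group is recorded as given its solvent alone. At both challenges, an effect on the osmotic response thus cannot be told apart from a solvent effect or a drug effect present without a challenge. The sterol synthesis list and the ER stress and ATF4 list were higher with the drug, by medians under 1 log unit. A feature unnamed here had the largest rise (1.19), and among features with a symbol the gelatinase gene Mmp9 rose most, by 0.78 ± 0.11 from 5.57 ± 0.11 to 6.35 ± 0.11 (SD, n = 3), followed by the potassium channel gene Kcnj8 (0.73 ± 0.12) and the prostacyclin receptor gene Ptgir (0.72 ± 0.09). Ficd, whose enzyme modifies the ER chaperone BiP, rose by 0.71 ± 0.14, and the fatty acid desaturase genes Scd and Fads2 rose by 0.67 ± 0.12 and 0.60 ± 0.06. Noxo1, an organizer of NADPH oxidase 1, had the largest fall (-1.0 ± 0.16), and the dipeptidase gene Dpep2 (-0.92 ± 0.12), the GTPase gene Rasl10a (-0.84 ± 0.08) and the chemokine gene Cxcl11 (-0.66 ± 0.08) also fell.

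Sterol synthesis genes rose in 7 of 18 cases, or 13 when adjusted over the list alone (median 0.26, camera adjusted p = 4.76e-20): Fdft1 by 0.41, Cyp51 by 0.39, Insig1 by 0.37, Sqle by 0.33 and Sc5d by 0.32. ER stress genes rose in 4 of 25, or 16 adjusted over the list alone (median 0.21, camera adjusted p = 2.38e-16), namely Dnajb9 (0.41), Hyou1 (0.36), Dnajc3 (0.32) and Hspa5 (0.21), all of which fold or guard proteins in the ER. Epithelial junction and keratin genes shifted down slightly, with 1 of 18 falling and 3 adjusted over the list alone (median -0.09, camera adjusted p = 0.000333), the faller being Krt19 (-0.28). Lists whose camera calls were lost with an estimated correlation were principal cell genes (median -0.10, camera adjusted p = 0.00206, but adjusted p = 0.058 with an estimated correlation) and fibroblast genes (median 0.10, camera adjusted p = 0.00237, but adjusted p = 0.178 with an estimated correlation). Leukocyte genes lost theirs as well (median -0.14, camera adjusted p = 0.00427, but adjusted p = 0.253 with an estimated correlation). The others were endothelial genes (median -0.10, camera adjusted p = 0.0084, but adjusted p = 0.255 with an estimated correlation) and cell cycle genes (median 0.06, camera adjusted p = 0.0158, but adjusted p = 0.498 with an estimated correlation). NRF2 genes were another (median 0.07, camera adjusted p = 0.0478, but adjusted p = 0.364 with an estimated correlation). The calcineurin and NFAT list, which holds genes of the pathway the drug inhibits, had a median of 0.03 (camera adjusted p = 0.316). Its transcripts do not measure the activity of the phosphatase. The osmolyte list had -0.02 (camera adjusted p = 0.404), with Akr1b1 at -0.05 and Slc5a3 at -0.20, neither past the test.

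At the 600 challenge limma called 116 features with the drug, 65 higher and 51 lower, with 2406 at an unadjusted p under 0.05. These calls rest on the spread pooled over all 18 arrays: a limma fit of only these 6 arrays called 0 (2170 unadjusted), and a plain 2-sample test per feature called 2 (2142 unadjusted). Leaving out an array gave 53, 51 or 67 calls (600 challenge replicates 1, 2 and 3) or 39, 62 or 51 (with the drug, replicates 1, 2 and 3). In the other direction, trended and robust moderation called 268, and a fit of features above the median level, where fewer are tested, called 262.

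At the 900 challenge cyclosporin A raised 5 chemokine genes by about 1 log unit besides shifting the sterol and ER stress lists. Cxcl6 rose by 1.43 ± 0.13, from 3.79 ± 0.25 to 5.22 ± 0.11 (SD, n = 3), Cxcl2 by 0.98 ± 0.19, Cxcl1 by 0.94 ± 0.07, Ccl20 by 0.92 ± 0.08 and Cxcl3 by 0.88 ± 0.14. Mmp9 rose by 1.14 ± 0.11, Scd by 0.81 ± 0.12, Ficd by 0.74 ± 0.14 and Insig1, the sterol-sensing brake on cholesterol synthesis, by 0.73 ± 0.08 on its more responsive feature. The largest falls among features with a symbol were in the protease gene Prss44 (-0.89 ± 0.17), Megf6 (-0.82 ± 0.15) and the protease gene Astl (-0.81 ± 0.16), dim features with levels of 2.20, 3.32 and 3.39 without the drug, and Cnn1 fell too (-0.76 ± 0.15).

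Sterol synthesis genes rose in 10 of 18 cases, or 15 adjusted over the list alone (median 0.27, camera adjusted p = 1.41e-23), among them Idi1 (0.53), Acat2 (0.52), Cyp51 (0.43) and Fdft1 (0.42). Inflammation genes rose in 6 of 17, or 15 rose and 1 fell adjusted over the list alone (median 0.25, camera adjusted p = 1.11e-16), including Il1b (0.68), the complement gene C3 (0.49) and Birc3 (0.37) with the chemokine genes. ER stress genes rose in 5 of 25, or 15 rose and 1 fell adjusted over the list alone (median 0.22, camera adjusted p = 1.82e-15), with Manf and Hsp90b1 both at 0.35. NRF2 genes rose in 2 of 19, or 13 adjusted over the list alone (median 0.17, camera adjusted p = 3.63e-12), namely Slc7a11 (0.67) and the mitochondrial superoxide dismutase gene Sod2 (0.28). The leukocyte list, whose markers had fallen after the challenge, did not pass with the drug (median 0.03 but mean -0.03, camera adjusted p = 0.841), with 1 of 13 rising, Fcer1g by 0.39, or 2 adjusted over the list alone. Interferon genes (median 0.10, camera adjusted p = 0.00521, but adjusted p = 0.298 with an estimated correlation) and principal cell genes (median -0.10, camera adjusted p = 0.0115, but adjusted p = 0.12 with an estimated correlation) lost their calls with the other correlation. Matrix genes did so too (median -0.03, camera adjusted p = 0.0201, but adjusted p = 0.41 with an estimated correlation). Calcineurin and NFAT genes had a median of 0.03 (camera adjusted p = 0.421) and osmolyte genes 0.04 (camera adjusted p = 0.801).

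Here limma called 143 features, 101 higher and 42 lower, with 2990 at an unadjusted p under 0.05. A limma fit of only these 6 arrays called 0 (2446 unadjusted), and a plain 2-sample test per feature called 0 (2621 unadjusted). Leaving out an array gave 68, 64 or 49 calls (900 challenge replicates 1, 2 and 3) or 43, 76 or 53 (with the drug, replicates 1, 2 and 3). Higher counts came from trended and robust moderation (385) and from features above the median level (405), where fewer are tested.

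Between the challenges, which share no array in these comparisons, 32 features were called with the drug in both and 31 moved the same way, 29 up and 2 down, where independent calls would share 0.232 and 0.0756. The calls share 1 variance estimate per feature, so the excess may be overstated. The shared rises included Fads2, Scd, Cyp51, Fdft1, Hspa5, Slc7a3, the PDGF receptor gene Pdgfrb and Mmp9, and the shared falls Dpep2 and Serpinb1a. Serpinb1a, as well as Fads2 and Slc7a3 at 900, were picked from the shared calls after their values were seen. Across all features the correlation of the drug effects was 0.049 (simulated range -0.024 to 0.024). The simulated noise was independent between features, which real features are not, so this range may be too narrow to judge so small a value. Each drug comparison was also set against the osmotic step of the other culture, with which it shares no array. Of 116 features called with the drug at 600, 69 were called in the step from 600, 49 the opposite and 20 the same way (r = -0.04 across all features). Of 143 at 900, 64 were called in the step from 300, 30 the opposite and 34 the same way (r = 0.005). The test of the difference between the drug effects called 13 features, 11 of them higher at the 900 challenge, with 2150 at an unadjusted p under 0.05. Cxcl6 differed by 1.55 ± 0.18 (adjusted p = 0.00342), its effect being -0.12 at the 600 challenge and 1.43 at the 900 challenge. Ccl20 differed by 1.06 ± 0.11 (-0.14 and 0.92), Cxcl11 by 0.99 ± 0.11 (-0.66 and 0.33) and Cxcl1 by 0.95 ± 0.10 (-0.01 and 0.94, the former 0.01 after quantile normalization). The interleukin gene Il1a differed by 0.85 ± 0.11 (-0.42 and 0.43) and Efhd1 by -0.62 ± 0.09 (0.27 and -0.35). The inflammation list was higher at 900 than at 600 in 4 of 17 cases, or 9 adjusted over the list alone (median 0.29, camera adjusted p = 3.22e-13). Leaving out an array of the 600 challenge gave 7 (replicate 1) or 5 (replicate 3) differing features, and of the 600 challenge with the drug 8, 6 or 4 (replicates 1, 2 and 3). Leaving out replicate 2 of the 900 challenge gave 8, leaving out replicate 1 or 3 of the 900 challenge with the drug gave 4, and a fit of only the 4 groups called 5. Counts were higher with trended and robust moderation (43), among features above the median level (44) and with 1 feature per gene (24).

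**Figure D3:**
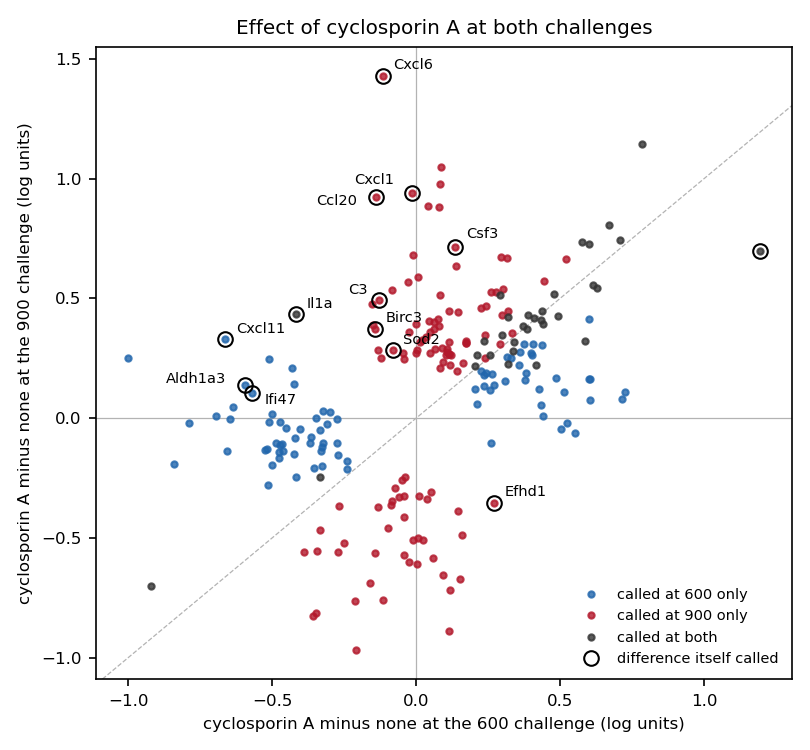
Effect of cyclosporin A in log units at the 600 challenge (horizontal axis) and at the 900 challenge (vertical axis) for the 227 features called in at least 1 of these tests, with circles around the 13 features whose effects differed between the challenges. Cxcl6 lies at -0.12 and 1.43, and 31 of the 32 features called in both lie on the same side of 0 on both axes.

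Culture at 600 instead of 300 mosmol/kg went with higher principal cell and interferon response genes and lower inflammation genes. Aqp2 was higher by 4.89 ± 0.14 log units (1.61 ± 0.12 against 6.50 ± 0.30, SD, n = 3), and the urea transporter gene Slc14a2 by 3.78 ± 0.11, from 1.98 in the 300 culture, where both lay under the lower quartile of the arrays. Lower in the 600 culture were the chemokine gene Cxcl6 (-4.28 ± 0.13), Olfm4, which encodes olfactomedin 4 (-3.87 ± 0.12), Ccl6 (-3.70 ± 0.15) and the cytokine gene Il1b (-3.49 ± 0.11).

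Principal cell genes were higher in 13 of 22 cases and lower in 1, or 14 and 1 adjusted over the list alone (median 0.84, camera adjusted p = 2.44e-11). Fxyd4 was at 3.17, the transcription factor gene Elf5 at 3.15, Aqp3 at 3.06, Aqp4 at 2.40 and Avpr2 at 2.33. All 19 measured interferon response genes were higher, also when adjusted over the list alone (median 0.92, camera adjusted p = 1.97e-18), among them Mx1 (3.17), Irf7 (2.49) and Ifit1 (2.14). Loop of Henle genes were higher in 6 of 10 and lower in 1, also when adjusted over the list alone (median 1.22, camera adjusted p = 1.39e-05). Junction and keratin genes were higher in 9 of 18 and lower in 4, also when adjusted over the list alone (median 0.18, camera adjusted p = 0.00107). Inflammation genes were lower in 14 of 17 and higher in 1 by either adjustment, the second adjusted over the list alone (median -0.82, camera adjusted p = 3.21e-13). Leukocyte markers were lower in 11 of 13, also when adjusted over the list alone (median -1.04, camera adjusted p = 1.54e-09). ER stress genes were lower in 9 of 25 and higher in 2, or 11 and 3 adjusted over the list alone (median -0.14, camera adjusted p = 0.0068). Fibroblast genes (median -0.27, camera adjusted p = 0.00527, but adjusted p = 0.148 with an estimated correlation) and matrix genes (median -0.38, camera adjusted p = 7.83e-06, but adjusted p = 0.105 with an estimated correlation) lost their calls with the other correlation. The intercalated cell list did not pass (median -0.04, camera adjusted p = 0.801), although Slc26a4, the pendrin gene of bicarbonate-secreting intercalated cells, had a difference of -2.54. Foxi1 (1.71 and 1.67 in the 300 and 600 cultures), Atp6v1b1 (2.26 and 2.12) and Rhcg (2.11 and 2.28) lay under the lower quartile of the arrays. Atp6v1c2 (3.19 and 3.22) lay above it. With such dim members the list says little about intercalated cells, and Slc26a4 alone does not mark them. limma called 4863 features, 2360 higher and 2503 lower, and 323 and 352 of them differed by at least 1 log unit.

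At the same final osmolality of 600 mosmol/kg, cells challenged for 24 h were compared with cells cultured there throughout. The challenged cells had lower Aqp2 (-4.21 ± 0.14), Fxyd4 (-3.49 ± 0.13) and Elf5 (-2.87 ± 0.12). They had higher Olfm4 (5.20 ± 0.12, from 2.21 ± 0.29 to 7.41 ± 0.08, SD, n = 3), Cxcl6 (4.24 ± 0.13) and Cxcl2 (3.30 ± 0.19). All 19 interferon genes were lower, also when adjusted over the list alone (median -1.33, camera adjusted p = 3.07e-22), as were 27 of 29 cell cycle genes, or 28 adjusted over the list alone (median -0.62, camera adjusted p = 7.26e-18). Principal cell genes were lower in 13 of 22 and higher in 1, or 14 and 2 adjusted over the list alone (median -0.79, camera adjusted p = 6.47e-10). Inflammation genes were higher in 14 of 17 and lower in 3, also when adjusted over the list alone (median 0.60, camera adjusted p = 4.75e-11). Endothelial genes (median -0.47, camera adjusted p = 4.11e-07) and junction and keratin genes (median -0.17, camera adjusted p = 0.000766) were lower as lists. Loop of Henle genes (median -0.79, camera adjusted p = 0.000666, but adjusted p = 0.0641 with an estimated correlation) and fibroblast genes (median -0.34, camera adjusted p = 0.000238, but adjusted p = 0.0641 with an estimated correlation) were called with the preset correlation. Matrix genes were higher by that test (median 0.12, camera adjusted p = 0.0309, but adjusted p = 0.449 with an estimated correlation). The leukocyte list did not pass here (median -0.12, camera adjusted p = 0.443). limma called 4655 features, 2179 higher and 2476 lower, with 202 and 388 at 1 log unit or more, against 3071 in a fit of only these groups and 2616 by a plain 2-sample test per feature.

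**Figure D4:**
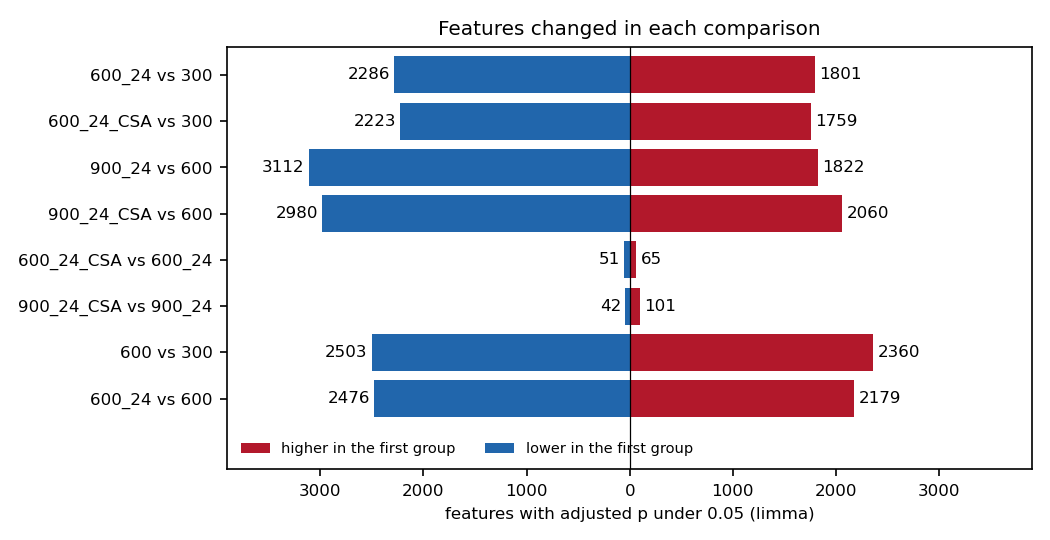
Number of features past the limma test (horizontal axis) that were higher (red) or lower (blue) in the first-named group of each of 8 comparisons (vertical axis). The 6 comparisons between cultures and challenges called 3982 to 5040 features, and the 2 comparisons of cyclosporin A against none called 116 and 143.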

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

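The tests of a ceiling and of leukocyte content in this part were chosen only after the result was seen.

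Cyclosporin A acted differently on a small set of genes at the 2 challenges, by a limma test of the difference itself. It singled out 13 features, and by the naming rule these were the chemokine genes Cxcl6 (1.55), Ccl20 (1.06), Cxcl11 (0.99) and Cxcl1 (0.95), the interleukin gene Il1a (0.85) and Efhd1 (-0.62), each as the effect at the 900 challenge minus that at the 600 challenge. The rest of the 13, named after their values were seen, were Aldh1a3 (0.73), Ifi47 (0.67), C3 (0.62), the granulocyte growth factor gene Csf3 (0.58), Birc3 (0.52), Sod2 (0.36) and a feature unnamed here (-0.50). Among the lists, inflammation differed by a median of 0.29 (camera adjusted p = 3.22e-13, also called with an estimated correlation). NRF2 genes differed by 0.13 (camera adjusted p = 5.96e-05, but adjusted p = 0.143 with an estimated correlation) and interferon genes by 0.18 (camera adjusted p = 0.000111, but adjusted p = 0.221 with an estimated correlation). The fibroblast list differed by -0.13 (camera adjusted p = 0.000252, but adjusted p = 0.155 with an estimated correlation) and the endothelium list by 0.07 (camera adjusted p = 0.00183, but adjusted p = 0.221 with an estimated correlation). Of 100 splits of the arrays, 1 gave as many features, the real split with 13, and the highest other count was 5. That share is the lowest that 100 splits can give. The splits concern the spread between these arrays, which may be technical, so a chance difference between cultures is not excluded. Without a single array the count ranged from 4 to 17. Of the 6 genes named by rule, 4 kept their call with each array left out in turn, and 4 in a fit of only the 4 groups.

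The chemokine part of this pattern was weighed further. Cxcl6 and Cxcl1 stood at 8.54 and 8.07 at the 600 challenge and at 3.79 and 5.70 at the 900 challenge, so a ceiling on genes already high is a candidate explanation. Against it, the 12 members of the inflammation list under level 7 at the 600 challenge had a median difference of effects of 0.39 (95% bootstrap interval 0.06 to 0.60), 9 of them above 0, and Ccl20 stood at 4.81. The interval treats members as independent and does not measure the spread between arrays. Since the members come from the list already called for this difference, the weight against a ceiling is limited. Added leukocytes in the 900 cultures with the drug would raise leukocyte markers too, but that list had a median of 0.03 (95% bootstrap interval -0.21 to 0.10) against 0.25 for inflammation, with 1 of 13 members rising (Fcer1g, 0.39), 2 adjusted over the list alone, and the abundant Lyz2 at -0.21 and Cd74 at 0.07. Some markers were dim there, such as Coro1a at 2.09 with the drug, and the interval treats members as independent. A modest gain of leukocytes is thus not excluded. A dependence of the drug effect on the final osmolality or on the starting culture may underlie the pattern and stays open as a hypothesis, since the design changes both together.

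The osmotic steps differed in 2148 features by the same kind of test. The step from 600 to 900 gave the higher value for Rnf186 (2.55), Ptges (2.5), C3ar1 (2.29) and Ccl6 (2.25), both near the lower quartile of the arrays in the 600 culture, and the myeloid kinase gene Fgr (2.13). It gave the lower value for Havcr1 (-2.03), Mmp3 (-1.92), Il24 (-1.89), Defb1 (-1.83) and the chloride channel accessory gene Clca4l (-1.78). Lists that differed also with an estimated correlation were ER stress and ATF4 (0.29), inflammation (0.36), principal cell genes (0.22) and prostaglandin genes (0.18). The interferon list (0.61, camera adjusted p = 5.91e-08, but adjusted p = 0.0691 with an estimated correlation) and the cell cycle list (0.26, camera adjusted p = 0.000301, but adjusted p = 0.265 with an estimated correlation) differed upward with the preset correlation. The extracellular matrix list (-0.26, camera adjusted p = 0.00157, but adjusted p = 0.265 with an estimated correlation) and the ion pump list (-0.15, camera adjusted p = 0.00686, but adjusted p = 0.112 with an estimated correlation) differed downward with it. Of 100 splits, 1 gave as many features, the real split with 2148, and the highest other count was 1. As above, the splits concern only the spread between these arrays and do not exclude a chance difference between cultures.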

How the results depend on the processing

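All alternative settings had been planned, and the check of whether replicate numbers pair the arrays and the tally of named genes that kept their calls were chosen only after the data were in hand. The counts for the osmotic steps moved with the variance model, and those for cyclosporin A rested on the spread pooled over 18 arrays. What drove each move was not tested beyond the construction named. Fits of only the groups compared, which have fewer arrays to estimate the spread, called 2479 (600 challenge with cyclosporin A against the 300 culture), 2860 and 3059 (900 challenge without and with the drug), and 3071 (600 challenge against the 600 culture). They called 0 and 0 by limma for cyclosporin A at the 600 and 900 challenges (2170 and 2446 at an unadjusted p under 0.05) and 5 for the difference of the drug effects. All 20 genes named in each comparison of a challenge with its culture kept their call in such fits, against 0 of 20 for each cyclosporin A comparison. A plain 2-sample test per feature on 6 arrays called 2588 and 2313 (600 challenge without and with the drug), 2593 and 2782 (900 challenge), 2616 (600 challenge against the 600 culture) and 2 and 0 for the drug (2142 and 2621 unadjusted). Among features above the median level, where fewer are tested, the drug counts were 262, 405 and, for the difference, 44, and with trended and robust moderation 268, 385 and 43. With 1 feature per gene the difference of the drug effects held 24 features.

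Leaving out each array in turn gave 3127 to 3451 features for the 600 challenge, 2991 to 3370 with the drug, and 3770 to 4326 for the 900 challenge, 3968 to 4349 with the drug. It gave 39 to 67 and 43 to 76 for the drug at the 600 and 900 challenges, 3976 to 4128 for the 600 culture against the 300 culture, 3798 to 3966 for the 600 challenge against the 600 culture, 4 to 17 for the difference of the drug effects and 1505 to 2008 for that of the steps. The number of lists called for the drug at the 900 challenge ranged from 4 to 10. Of the genes named for these drug effects, 10 of 20 (600) and 7 of 20 (900) kept their call without any array.

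With an estimated correlation the count of lists went from 10 to 6 and from 12 to 7 (600 challenge without and with the drug), from 9 to 3 and from 7 to 4 (the drug at 600 and 900), from 5 to 1 (difference of drug effects) and from 8 to 4 (difference of steps). The rotation test fry, which does not compare a list with other genes, called 18, 20, 18, 18 and 14 (600 challenge, 900 challenge, 600 against 300 culture, 600 challenge against 600 culture, difference of steps). Its direction was opposite to camera's in 8 cases, none called by camera. In 5 of them fry did not pass either, and in 3 it did: junction and keratin genes (600 challenge with the drug, median -0.03), prostaglandin genes (600 against 300 culture, -0.17) and intercalated cell genes (600 challenge against 600 culture, -0.12); the cause was not tested. After quantile normalization Cxcl1 with the drug at the 600 challenge had 0.01, Gapdh at the 900 challenge 0, and the correlation of the 600 challenge with the drug effect at 900 was -0.006, all close to 0 before as well. Among features above the median level the correlation of the steps was 0.559 and that of the drug effects 0.199.

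The replicate numbers, taken from the titles, do not pair the arrays. For the third arrays of both 900 challenge groups the source names give 9 instead of 3, so these numbers are in doubt, and the block with them. Over 15 pairs of groups the correlation of same-numbered deviations ran from -0.129 to 0.108, and 7 of 18 arrays lay closest to their own number. With the replicate number as a block, all 10 counts stayed within 1.5 times the reported ones, for example 91 and 119 for the drug and 9 for the difference of its effects. Quantile normalization, centring and array weights kept all 10 feature counts within that range. The pseudocount alternative was not run, since the values are already logarithms. Signal over background is not given in the sources used here, and dim features had the larger spread, with a median SD of 0.194 to 0.222 under level 3 against 0.0345 to 0.0474 at level 6 or more.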

Other observations

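The tests of an even leukocyte loss, of the principal cell list against the junction and keratin list, and of interferon genes after the 600 challenge were chosen only after the result was seen.

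Acta2 and Tagln, members of the fibroblast and interstitium list picked after their values were seen, fell after both challenges as that list did. The actin gene Acta2 had differences of -0.71 at the 600 challenge and -0.86 at the 900 challenge, and the actin-binding Tagln -0.91 and -1.19. With cyclosporin A at the 900 challenge, Tagln (-0.57), Acta2 (-0.46) and Ccn2 (-0.51) fell further against the challenge alone, while Pdgfrb of the same list as Tagln rose (0.32). The fibroblast list itself did not pass there, with 1 of 16 rising and 2 falling, also when adjusted over the list alone (median 0.03 but mean -0.05, camera adjusted p = 0.709). At the 600 challenge Tagln (-0.04) and Acta2 (-0.10) did not pass the test, and the difference of the Tagln effects (-0.53) did not pass either. Between the 600 culture against the 300 culture and the 900 challenge against the 600 culture, 2251 features were called in both, 769 up and 1079 down in both, against 152 and 275 for independent calls, and 403 moved in opposite directions. These comparisons share the 600 arrays with opposite sign, which alone gives a correlation of -0.499 in simulations, and the observed correlation across features was 0.228. Aqp2 (4.89 and 1.44), Slc14a2 (3.78 and 1.25) and the mucin gene Muc1 (2.07 and 1.23) rose in both. The challenged cells at 600 mosmol/kg held less Aqp2 than the 600 culture (-4.21), so these comparisons mix culture history with osmolality.

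Genes often used as references did not all stay level. Hprt1 had differences of -0.37 at the 600 challenge, -0.90 at the 900 challenge and -0.90 in the 600 culture against the 300 culture, and kept its sign after quantile normalization and after centring of the arrays. The glycolytic gene Pgk1 fell by 0.46 at the 600 challenge and had 0.10 at the 900 challenge, which did not pass, and Gapdh, on the feature in that list, had -0.04 and 0.06, neither past the test. The list of reference genes had medians of -0.09 (camera adjusted p = 0.135) and -0.05 (camera adjusted p = 0.206) in these steps. For hypoxia and glycolysis the medians were -0.06 (camera adjusted p = 0.314) and 0.05, with a mean of -0.01 (camera adjusted p = 0.231), and Vegfa rose by 0.59 in the second. Mitochondrial respiration had -0.01 (camera adjusted p = 0.864) and 0.05 (camera adjusted p = 0.0783), and p53 and DNA damage genes had 0.00, with a mean of -0.06 (camera adjusted p = 0.845), and -0.19 (camera adjusted p = 0.0634). Proximal tubule markers had -0.03, with a mean of 0.04 (camera adjusted p = 0.535), and 0.07 (camera adjusted p = 0.137). Slc34a1 (2.04 and 1.93 in the 300 and 600 cultures) and Lrp2 (2.33 and 2.44) lay under the lower quartile of the arrays. Slc13a1 (3.31 and 3.16) lay above it. With such dim members the list says little about proximal tubule cells.

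Leukocyte markers fell after both challenges (medians -1.19 and -1.12) in cultures whose labels name collecting duct cells and no sorting step. In the 300 culture the most abundant members stood at 7.76 (Lyz2), 6.93 (Cd74), 6.81 (Fcer1g) and 6.61 (Cd68), and 0 members belong to another list, while how many of them collecting duct cells express was not analysed here. A normalization that depends on level is argued against, since the list lay at percentile 0 of 10000 random lists of matched level in both steps, whose lowest medians were -0.60 and -0.35. Members at level 5 or more differed in their falls beyond their errors by a chi-square test of heterogeneity, from -0.24 to -1.70 over 9 members (heterogeneity p = 2.31e-44) and from -0.34 to -1.88 over 6 members (heterogeneity p = 4.43e-61). Features differ in background and response, so this does not decide, and a loss of leukocytes, even or not, and lower expression within them cannot be told apart here.

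Principal cell genes were higher in the 600 culture than in the 300 culture, where leukocyte markers were lower. If a smaller share of other cells were the cause, junction and keratin genes would be higher by a like amount where features respond alike. The mean of the principal cell list exceeded that of the junction and keratin list by 0.96 (2-sided permutation test with 100000 permutations over genes, p = 0.0187), genes not being independent replicates. The lists held features at unlike levels, with Aqp2 at 1.61 and Slc14a2 at 1.98 in the 300 culture against Epcam at 7.97 and Krt18 at 8.25. Features differ in background and response, so the test does not decide whether a smaller share of other cells was the cause. The labels do not say whether these cultures came from the same cell preparation, so a difference between preparations and the osmolality of culture cannot be told apart.

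Interferon response genes were higher in the 600 culture, and the hypothesis that 24 h at 600 mosmol/kg raises them in cells of the 300 culture was tested. The list went the other way after the 600 challenge, with a median of -0.24, 7 of 19 members falling and 0 rising. The bootstrap interval of -0.36 to -0.13 (95%) treats the members as independent, and the camera call was lost with an estimated correlation (adjusted p = 0.331). The rotation test fry, which keeps the correlation between genes, also gave a fall (adjusted p = 0.00122), so a rise is argued against while the size of the fall is less sure. An effect of longer culture at 600 mosmol/kg, or a difference between preparations, may lie behind the higher level and was not tested.

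For the 8 comparisons between pairs of groups, the 10 splits of the 6 arrays are too few for a share under 0.05. Every other split also mixes arrays of both groups, which adds any difference between them to the spread and lowers its count. The low counts of the other splits are thus no evidence for the real ones. The real count was 4087 for the 600 challenge (highest other split 1), 3982 with cyclosporin A (1), 4934 for the 900 challenge (1) and 5040 with cyclosporin A (0). It was 116 for cyclosporin A at the 600 challenge (1), 143 at the 900 challenge (5), 4863 for the 600 culture against the 300 culture (0) and 4655 for the 600 challenge against the 600 culture (0).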
